A study of Homo sapiens with 18 samples.

How the data were processed

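Gene expression was measured on Affymetrix U133 Plus 2.0 arrays in DU145 and CWR22Rv1, a pair of established human prostate cancer cell lines. Per the labels' protocols, cells were transfected with Lipofectamine and an siRNA with a scrambled sequence, an siRNA against Stat3 or siRNA against Stat5a/b, and were harvested 48 h later. Total RNA was column-purified with DNase treatment, biotin-labelled as cRNA and hybridised, per the labels. Each of the 6 groups held 3 arrays, 18 in all. The labels describe triplicates whose RNA was not pooled, but do not say that they came from separate cultures. P-values therefore measure the spread between these samples, which may be technical.

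The deposited values are log2 expression values per probe set, and the submitters' processing notes name RMA and limma without versions. RMA corrects the background, quantile-normalises the arrays and summarises the probes of a probe set. The deposited log2 values ran from 1.54 to 14.3, with array medians between 5.16 and 5.20, and were used without further scaling. Detection calls were not used here, so no probe set was left out as dim, and how far each value lay above background is unknown. The number of arrays per group limits the precision: the quartiles of the standard error of a log2 change over genes were 0.076 and 0.13.

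The table held 54675 probe sets. The platform's probe annotation gave 1 gene symbol to 41091 of them, several to 1801 and none to 11721, and 62 were control probe sets. Symbols were compared with a RefSeq gene table of assembly GRCh38.p14 through Entrez identifiers, of which 41037 matched and 0 led to another symbol. Each of 19775 genes was represented by its single-symbol probe set with the highest mean over all 18 arrays. For 10523 genes this was a choice among more than 1 probe set. A gene without such a probe set is unnamed here, and probe sets with several or no symbols stayed out of gene counts. Some probe sets, among them those of AKR1C1, AKR1C2, CXCL8, CLDN3 and FTL, can hybridise with related transcripts, so their values may mix genes.

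One linear model per gene with a mean for each of the 6 groups was fitted to all 18 arrays in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 12 residual and 3.82 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within a comparison, and a gene was called at an adjusted p under 0.05. Comparisons were each siRNA against the line's scramble control, Stat5a/b against Stat3 siRNA within a line, and the difference of each siRNA's effect between the lines. Control arrays of the lines were compared for description. Values given as a ± b are a log2 change of 3 arrays against 3, or its difference between the lines, and the standard error from this fit. That error pools the spread of all 6 groups, so it is the same in every 3-against-3 comparison of a gene. It does not measure the spread of the arrays compared. As DU145 arrays were mostly more spread than CWR22Rv1 arrays, errors and p-values tend to be too small in DU145 and too large in CWR22Rv1. Percentages of control are 2 raised to the log2 change.

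The design, the alternatives and 35 gene lists were fixed before the data were examined. The lists covered the siRNA targets, other STAT genes, JAK-STAT receptors, kinases and regulators, textbook STAT3 targets, textbook STAT5 targets, DNA replication and G1/S, mitosis and G2/M, cyclin-dependent kinase inhibitors, apoptosis regulators, interferon-stimulated genes, NF-kB target and inflammatory genes, androgen-responsive genes, luminal and epithelial genes, mesenchymal genes, and proteases of invasion with their inhibitors. They further covered TGF-beta targets, the unfolded protein and integrated stress response, heat shock proteins, NRF2 targets, sterol biosynthesis, p53 targets, hypoxia targets, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, the proteasome, replication-dependent histones, MAPK immediate-early and feedback genes, the RNA interference machinery and housekeeping controls. Markers of neuroendocrine, basal, fibroblast, endothelial and leukocyte cells completed them. List shifts were tested with camera in limma with its preset correlation between genes of 0.01, adjusted over all lists and the 6 siRNA comparisons. An estimated correlation and fry were the alternatives; fry tests whether a list's genes move on balance one way, not whether they move more than other genes.

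Genes were named by a fixed rule. Per siRNA and line it takes the targeted genes, and the 10 largest rises and 10 largest falls among called genes whose 3 siRNA arrays all lay beyond the 3 control arrays. It adds up to 4 called members, by smallest adjusted p, of each list that was called or held 3 or more called members, and uncalled members among SOCS3, CISH, BCL2L1, CCND1, MYC, BIRC5, MCL1, PIM1, KLK3, CDH1, VIM, MMP9 and CDKN1A. Between siRNAs and between lines it takes the 5 largest changes each way, and for overlaps the 10 shared genes with the largest smaller change. For the level differences between lines, genes of the luminal, mesenchymal, androgen-responsive and STAT lists were described. Genes outside the rule are said to be chosen after their values were seen.

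Alternatives were a fit within each line, the replicate number as a block, array weights, a trended robust variance, renewed quantile normalisation, cyclic loess within each line, the mean of a gene's probe sets, all probe sets, a filter on dim genes, stricter thresholds, and leaving out each array. Arrays of a group are numbered 1 to 3. Between DU145 control and Stat3 siRNA, the deviations of same-numbered arrays from their group means correlated at 0.158 to 0.328 over genes. All 3 pairs lay over the limit of 0.1 for pairing, and 6 of 6 arrays correlated best with their own number. This pairing comes from the values, not from the labels, so the block is given beside results of this comparison where it changed a call or moved a count of 3 or more members by over 1.5 times. Overlaps of comparisons that share control arrays were set beside 100 simulated draws of unchanged groups. The test was tried on simulated data for Stat3 siRNA in DU145 with 19775 genes, 50 of them changed at each fold. In that simulation it recovered 26%, 86%, 98% and 100% of changes of 1.25, 1.5, 2 and 3-fold, and 3.73% of its calls were false. These rates hold for the simulated noise only, and do not show recovery or false calls in the real DU145 arrays. The real arrays were mostly more spread than those of CWR22Rv1, and same-numbered arrays correlated. With DU145 fitted alone, the 3117 genes called for Stat3 siRNA became 1549. The list test, simulated for Stat5a/b siRNA in DU145, called the 1 shifted list and 0 lists in the other comparisons against control. The simulated noise was independent between genes, whereas the estimated correlation was 0.43 for interferon-stimulated genes and 0.47 for MAPK genes. That trial therefore cannot show how the list test fares with correlated genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.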

Results

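The data comprised 18 arrays of 54675 probe sets, 3 for each of 6 groups. DU145 and CWR22Rv1 cells received scramble control siRNA, Stat3 siRNA or Stat5a/b siRNA and were harvested after 48 h. DU145 was derived from a brain metastasis of prostate carcinoma and is androgen-insensitive, whereas CWR22Rv1 comes from a relapsed prostate xenograft and retains luminal features. Arrays of one group correlated at 0.993 to 0.998 across probe sets, and arrays of different lines at 0.909 to 0.916, the probe sets not being independent replicates. The 3' minus 5' difference of the control probe sets ran from 0.041 to 0.15 for GAPDH and from 0.45 to 0.85 for ACTB. In the ACTB probe sets its group means were 0.546, 0.559 and 0.593 in DU145 control, Stat3 and Stat5a/b arrays, and 0.760, 0.740 and 0.797 in the CWR22Rv1 arrays. The comparisons asked which transcripts follow loss of Stat3 or of Stat5a/b, latent transcription factors activated by cytokine and growth factor receptors, and how far these responses meet within and between the lines.

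Stat3 siRNA lowered STAT3 to 32.6% of control in DU145 (-1.62 ± 0.090, adjusted p = 1.1e-08) and to 45.7% in CWR22Rv1 (-1.13 ± 0.090, adjusted p = 2.5e-06). Its log2 values were 10.91, 10.96 and 10.82 in the DU145 control arrays and 9.45, 9.19 and 9.20 with Stat3 siRNA. In CWR22Rv1 they were 7.40, 7.21 and 7.24 against 6.04, 6.31 and 6.11. Stat5a/b siRNA lowered STAT5B to 39.1% of control in DU145 (-1.36 ± 0.091, adjusted p = 3.4e-08) and to 53.4% in CWR22Rv1 (-0.91 ± 0.091, adjusted p = 1.2e-05). All 3 siRNA arrays lay below all 3 control arrays in each of these comparisons. Other STAT5B probe sets gave 44.4% and 64.6% of control in DU145 and 52.5% and 59.9% in CWR22Rv1, and a pair did not fall (0.24 and 0.42, then 0.10 and 0.052, none called). The mean of all its probe sets therefore changed less, by -0.50 (adjusted p = 2.2e-04) and -0.48 (adjusted p = 0.00134). STAT5A, at mean control values of 6.16 and 6.31, did not pass the test with its own siRNA (-0.30 ± 0.13, adjusted p = 0.101 in DU145, and -0.34 ± 0.13, adjusted p = 0.146 in CWR22Rv1). With DU145 fitted alone its adjusted p was 0.0263. Neither siRNA moved the other target past the threshold: STAT5B measured -0.10 and -0.12 with Stat3 siRNA, STAT5A 0.023 and -0.12, and STAT3 0.16 and 0.13 with Stat5a/b siRNA, in DU145 and CWR22Rv1. Among other probe sets of STAT3, a pair gave 27.0% and 30.2% of control in DU145 and 30.9% and 39.5% in CWR22Rv1. A further STAT3 probe set was not called lower with Stat3 siRNA (-0.36, adjusted p = 0.665 in DU145). Its DU145 arrays stood at 4.12, 4.46 and 4.36 with Stat3 siRNA and at 4.51, 4.83 and 4.68 in control. It was higher with Stat5a/b siRNA in DU145 (1.31, adjusted p = 0.0286), where replicate 3 stood at 7.53 and the others at 5.13 and 5.28.

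**Figure D1:**
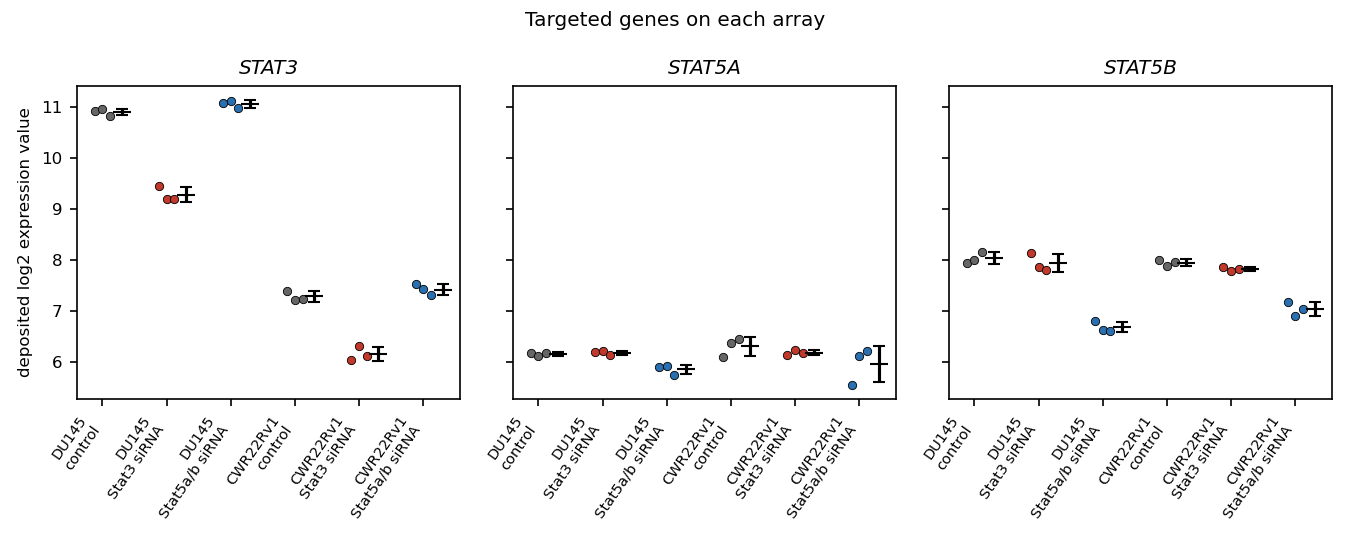
Deposited log2 values of STAT3, STAT5A and STAT5B on each array of the 6 groups, with bars at the mean ± SD of 3 arrays. STAT3 averaged 10.90 in DU145 control arrays and 9.28 with Stat3 siRNA, and 7.28 and 6.15 in CWR22Rv1.

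Against control, 3117 genes changed with Stat3 siRNA in DU145 (1486 higher, 1631 lower), 4805 with Stat5a/b siRNA in DU145 (2334 and 2471), 944 with Stat3 siRNA in CWR22Rv1 (544 and 400) and 1277 with Stat5a/b siRNA in CWR22Rv1 (624 and 653). At least 2-fold changes numbered 93, 168, 9 and 17. The siRNA and control arrays did not overlap for 26.2%, 34.4%, 32.3% and 31.1% of genes, where chance gives 10% for 3 against 3. The spread between replicate arrays was larger in DU145 (median gene SD 0.112, 0.126 and 0.114) than in CWR22Rv1 (0.0724, 0.0731 and 0.0824). Fitted alone, DU145 gave 1549 and 2877 genes and CWR22Rv1 2059 and 2372, with 1528, 2831, 920 and 1247 called in both fits, so counts are not compared between lines. Leaving out one array left 448 (without control replicate 3) to 547 genes (without Stat3 siRNA replicate 2) of the 944, and 718 (without control replicate 1) to 844 (without Stat5a/b siRNA replicate 1) of the 1277. For Stat3 siRNA in CWR22Rv1 the excess of higher genes turned with scaling, to 426 higher and 496 lower after quantile normalisation and 438 and 498 after cyclic loess. The smaller lead of lower genes in the other comparisons turned too, to 1615 higher and 1600 lower, 2631 and 2293, and 712 and 625 after quantile normalisation.

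In DU145, Stat3 siRNA raised the co-stimulatory receptor TNFRSF9 (1.99 ± 0.15), the G1 kinase CDK6 (1.96 ± 0.14), the anti-apoptotic BCL2A1 (1.77 ± 0.23) and the neutrophil chemokine CXCL8 (1.65 ± 0.37). The methionine salvage enzyme MTAP (1.56 ± 0.091), the transcription factor SOX9 (1.45 ± 0.20), the disintegrin metalloprotease ADAM12 (1.39 ± 0.084), MDFIC (1.33 ± 0.062) and the noncoding LINC00973 (1.95 ± 0.19) rose as well. Mucosal keratin KRT4 (-1.77 ± 0.31), the FGF carrier FGFBP1 (-1.56 ± 0.17), selenoprotein P gene SELENOP (-1.45 ± 0.21), chromatin proteins BCL7B (-1.45 ± 0.10) and HMGN5 (-1.41 ± 0.13), and the metallothionein MT1M (-1.35 ± 0.31) fell. So did the thrombin receptor family member F2RL2 (-1.38 ± 0.20), the calcium-binding RCN2 (-1.32 ± 0.051) and C1orf115 (-1.31 ± 0.077). Adjusted p ranged from 4.8e-10 for RCN2 to 0.00610 for MT1M among the rises and falls just named, 0.00526 being that of CXCL8, and each lay beyond control in 3 of 3 arrays, as the naming rule requires. G0S2, a lipase inhibitor, was also higher (1.44), but its adjusted p was 0.0529 without control replicate 1 and 0.0513 without Stat3 siRNA replicate 3.

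Cell cycle lists rose with Stat3 siRNA in DU145. Of 33 replication and G1/S genes 12 rose and 0 fell, 17 and 0 when adjusted over the list alone (median 0.17, camera adjusted p = 8.3e-09). Origin licensing factor CDC6 (0.66 ± 0.058), helicase subunits GINS2 (0.63 ± 0.051) and GINS1 (0.63 ± 0.062), and the flap nuclease FEN1 (0.43 ± 0.053) were among them. Of 30 mitotic genes 18 rose and 1 fell, 21 and 1 adjusted over the list alone (median 0.21, adjusted p = 8.3e-09), including PRC1 (0.36 ± 0.057), CDK1 (0.32 ± 0.055), BUB1B (0.29 ± 0.052) and CCNB1 (0.31 ± 0.054). Both calls held with an estimated correlation (adjusted p = 0.0342 and 0.0429). Replication-dependent histones gave 5 rises and 0 falls of 10 (5 and 0 adjusted over the list alone, adjusted p = 0.00582, and 0.111 with an estimated correlation), among them H2BC12 (0.39 ± 0.063) and H2AC6 (0.32 ± 0.059). The histone rises numbered 3 and 2 without control replicates 1 and 3, and 2 and 3 without Stat3 siRNA replicates 2 and 3.

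Some inflammatory and growth signalling genes rose in the same arrays, without a list call that held with an estimated correlation. NF-kB targets gave 7 rises and 0 falls of 22 (9 and 0 adjusted over the list alone), with the inhibitor NFKBIA (0.66 ± 0.094), the chemokine CCL20 (0.43 ± 0.077), LTB (0.53 ± 0.11) and IER3 (0.56 ± 0.12). MAPK immediate-early and feedback genes gave 7 and 0 of 21 (7 and 0 adjusted over the list alone), with feedback inhibitors SPRY2 (0.77 ± 0.14) and SPRED2 (0.69 ± 0.067) and the AP-1 member FOSL1 (0.78 ± 0.17). The MAPK rises numbered 4 without control replicate 2, 11 without control replicate 3, and 11 with the replicate number as a block. Camera adjusted p was 0.00582 and 1.9e-04, and 0.296 and 0.487 with an estimated correlation.

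Some epithelial, redox, sterol and chaperone genes fell with Stat3 siRNA in DU145, a minority of each list when adjusted over all genes. Luminal and epithelial genes gave 1 rise and 6 falls of 19 (1 and 7 adjusted over the list alone), among them E-cadherin CDH1 (-0.98 ± 0.078), EPCAM (-0.49 ± 0.082), SPINT1 (-0.44 ± 0.088) and the tight junction gene CLDN7 (-0.41 ± 0.061). NRF2 targets gave 0 and 6 of 17 (0 and 9), with GCLC (-0.40 ± 0.066) of glutathione synthesis, the malic enzyme ME1 (-0.41 ± 0.067), the cystine carrier SLC7A11 (-0.60 ± 0.10) and NQO1 (-0.31 ± 0.059). Sterol biosynthesis gave 0 and 8 of 20 (1 and 11), with MSMO1 (-0.52 ± 0.12), DHCR7 (-0.34 ± 0.064) and SC5D (-0.30 ± 0.062), and heat shock proteins 0 and 4 of 10 (0 and 5), with DNAJA1 (-0.37 ± 0.050) and HSPA4 (-0.40 ± 0.055), the bracketed pairs adjusted over the list alone. Camera adjusted p for these lists was 8.0e-04, 0.00125, 0.0161 and 0.00881, but with an estimated correlation adjusted p was 0.117, 0.296, 0.337 and 0.276. The sterol call ended without Stat3 siRNA replicate 2 (adjusted p = 0.0513). Sterol falls numbered 4 without control replicate 1 and 5 without control replicate 2 or 3 or Stat3 siRNA replicate 2 or 3, and heat shock falls 2 without control replicate 3. Interferon-stimulated genes gave 0 rises and 4 falls of 36 (0 and 3 adjusted over the list alone), including GBP1 (-0.84 ± 0.18), BST2 (-0.71 ± 0.17) and USP18 (-0.46 ± 0.081). Its adjusted p of 0.0263 was 0.712 with an estimated correlation, 0.590 without Stat3 siRNA replicate 3, and 0.171 and 0.0662 without control replicates 2 and 1. On the arrays the list averaged -0.12, -0.038 and -0.50 relative to the control mean, and the same-numbered control arrays 0.054, 0.12 and -0.17, so it was lower in all 3 pairs. With the replicate number as a block 13 members fell (camera adjusted p = 0.00203).

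Lists named for STAT3 went both ways in DU145. Textbook STAT3 targets gave 2 rises and 5 falls of 29 (3 and 5 adjusted over the list alone, camera adjusted p = 0.661). The mucin MUC1 (-0.91 ± 0.14), the angiogenic factor VEGFA (-0.63 ± 0.099) and the kinase PIM1 (-0.41 ± 0.073) fell and the G1 cyclin CCND1 (0.32 ± 0.061) rose. SOCS3 measured -0.083, BCL2L1 -0.081, MYC 0.21, BIRC5 0.026, MCL1 0.21, MMP9 0.11 and CISH -0.079, none past the test. With the replicate number as a block MCL1 passed (adjusted p = 0.0279) and 4 textbook targets rose. Among receptors, LIFR (-1.15 ± 0.093) and IFNGR1 (-0.55 ± 0.066) fell and IL6R (0.82 ± 0.068) and IFNAR1 (0.47 ± 0.078) rose. Other called genes were the cell cycle inhibitors CDKN1A (0.49 ± 0.091), CDKN3 (0.31 ± 0.065) and CDKN2D (-0.50 ± 0.11), the death regulators BCL2L11 (-0.79 ± 0.067), TNFRSF10B (0.75 ± 0.067) and APAF1 (0.57 ± 0.13), the matrix genes COL1A1 (-1.24 ± 0.11), THBS1 (-1.07 ± 0.17) and LOX (1.19 ± 0.17), heparanase HPSE (-1.04 ± 0.093), and the p53 targets CCNG1 (0.75 ± 0.054) and TP53I3 (-0.97 ± 0.11).

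In DU145, Stat5a/b siRNA raised the interferon-induced CMPK2 (2.47 ± 0.14), MX1 (1.89 ± 0.23), IFI27 (1.94 ± 0.38), IFIT2 (1.59 ± 0.19) and XAF1 (1.54 ± 0.15), the glucose-responsive arrestins TXNIP (2.24 ± 0.096) and ARRDC4 (1.80 ± 0.12), the actin linker AFAP1 (2.08 ± 0.30), C9orf152 (2.05 ± 0.31) and LINC00115 (1.65 ± 0.27). The largest falls were KRT4 (-2.32 ± 0.31), CCN5 (-1.85 ± 0.15), the hyaluronidase-like CEMIP2 (-1.79 ± 0.13), FGFBP1 (-1.72 ± 0.17), CA11 (-1.71 ± 0.18) and the trafficking GTPase RAB31 (-1.70 ± 0.13). They were followed by OGFRL1 (-1.69 ± 0.086), the retinoic acid enzyme ALDH1A3 (-1.63 ± 0.13), ENPP4 (-1.55 ± 0.077) and DHCR7 (-1.50 ± 0.064), which makes the last step of cholesterol synthesis. CMPK2 averaged 4.21 in control and 6.68 with the siRNA (adjusted p = 9.8e-09), and DHCR7 10.29 and 8.79 (adjusted p = 7.8e-10). Each of these genes lay beyond control in 3 of 3 arrays, as the naming rule requires.

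Of 36 interferon-stimulated genes 22 rose and 1 fell with Stat5a/b siRNA in DU145, 26 and 1 adjusted over the list alone (median 0.64, camera adjusted p = 2.5e-11), including IRF9 (1.06 ± 0.075) and USP18 (0.85 ± 0.081). With an estimated correlation adjusted p was 0.296. Relative to the DU145 control mean, the list averaged 0.97, 0.94 and 0.45 on replicates 1, 2 and 3 with Stat5a/b siRNA, 0.054, 0.12 and -0.17 on the control arrays, and -0.12, -0.038 and -0.50 with Stat3 siRNA, replicate 3 being lowest in each group. The receptor chain IFNAR1 (-1.22 ± 0.078) fell. Whichever of the 6 arrays was left out, at least 20 members rose.

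Sterol biosynthesis fell with Stat5a/b siRNA in DU145: 15 of 20 genes fell and 0 rose, 15 and 0 adjusted over the list alone (median -0.50, adjusted p = 5.4e-10, and 0.0362 with an estimated correlation). Squalene epoxidase SQLE (-1.02 ± 0.095), lanosterol synthase LSS (-0.84 ± 0.072) and SC5D (-0.49 ± 0.062) joined DHCR7. Glycolysis gave 0 rises and 7 falls of 19 (0 and 9 adjusted over the list alone, adjusted p = 8.0e-04, and 0.386 with an estimated correlation), with PFKM (-0.65 ± 0.071), ENO2 (-0.63 ± 0.12), PFKP (-0.49 ± 0.091) and GPI (-0.37 ± 0.079). Luminal and epithelial genes gave 2 and 10 of 19 (2 and 11 adjusted over the list alone, adjusted p = 3.3e-04, and 0.104 with an estimated correlation), with CDH1 (-1.18 ± 0.078), SPINT1 (-0.70 ± 0.088), OCLN (-0.61 ± 0.063) and CLDN7 (-0.48 ± 0.061). TGF-beta targets gave 1 and 5 of 17 (1 and 5 adjusted over the list alone, adjusted p = 0.0221, and 0.111 with an estimated correlation). TGFBR1 (-0.78 ± 0.11), TGFB2 (-0.74 ± 0.14) and TGFBR2 (-0.47 ± 0.092) fell, but the list's adjusted p was 0.0715 without Stat5a/b siRNA replicate 2 and 0.0613 without control replicate 3.

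Stress response, cell cycle and MAPK lists were called higher with Stat5a/b siRNA in DU145 with the preset correlation but not with an estimated one. The unfolded protein and integrated stress response gave 13 rises and 6 falls of 24 (13 and 6 adjusted over the list alone), with HERPUD1 (0.75 ± 0.067) of ER-associated degradation, the pseudokinase TRIB3 (0.70 ± 0.065), and amino acid enzymes ASNS (0.74 ± 0.075) and PSAT1 (0.49 ± 0.050). NRF2 targets gave 10 and 2 of 17 (10 and 2), with SRXN1 (1.02 ± 0.048), AKR1C1 (1.13 ± 0.071), AKR1C2 (0.78 ± 0.11) and SLC7A11 (0.74 ± 0.10). Replication genes gave 16 and 1 (19 and 3), with CCNE2 (1.26 ± 0.12), CDC6 (0.54 ± 0.058), GINS1 (0.53 ± 0.062) and UNG (0.52 ± 0.052), mitotic genes 14 and 2 (16 and 2), with CCNA2 (0.43 ± 0.072) and UBE2C (0.32 ± 0.063), and MAPK genes 8 and 0 (8 and 0), with ETV5 (0.71 ± 0.085) and SPRY2 (0.63 ± 0.14), the bracketed pairs adjusted over the list alone. Camera adjusted p for these 5 lists was 0.00398, 2.4e-04, 1.0e-04, 0.00205 and 0.00376, but with an estimated correlation adjusted p was 0.211, 0.243, 0.104, 0.260 and 0.604. Without Stat5a/b siRNA replicate 3 the MAPK list's adjusted p was 0.138. Its rises numbered 5, 4 and 5 without control replicate 1, control replicate 2 and Stat5a/b siRNA replicate 3, and mitotic rises 8 and 9 without control replicate 1 and Stat5a/b siRNA replicate 1.

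Textbook STAT5 targets gave 5 rises and 2 falls of 20 with Stat5a/b siRNA in DU145 (6 and 3 adjusted over the list alone, camera adjusted p = 0.871). CCND1 (-0.57 ± 0.061) and PIM2 (-0.45 ± 0.064) fell and CEBPB (0.54 ± 0.058) and BCL6 (0.34 ± 0.078) rose. CISH, a feedback inhibitor and classic STAT5 target, measured 0.17 ± 0.060 (adjusted p = 0.0566, and 0.0468 without control replicate 1), and SOCS3 -0.018, MYC 0.26, BIRC5 0.042, PIM1 0.075, MMP9 0.12 and VIM 0.11 did not pass. Prosurvival MCL1 (0.49 ± 0.079) rose and BCL2L2 (-1.21 ± 0.076) fell, IL6R (0.78 ± 0.068) rose, and the phosphatase PTPN6 (-0.62 ± 0.085) fell. The calcium-binding S100A4 (-1.06 ± 0.16) and fibronectin FN1 (-0.53 ± 0.089) fell, whereas the E-cadherin repressor ZEB1 (0.62 ± 0.13) rose. Of RNA interference genes AGO4 (0.86 ± 0.084) rose and AGO2 (-0.80 ± 0.16), AGO1 (-0.43 ± 0.087) and DICER1 (-0.43 ± 0.081) fell. ELL2 (-0.96 ± 0.16), ABCC4 (-0.56 ± 0.089), FKBP5 (-0.35 ± 0.079) and TPD52 (-0.30 ± 0.065) of the androgen-responsive genes fell, while KLK3 measured 0.18. The hypoxia-responsive BNIP3L (-0.96 ± 0.077) and P4HA1 (-0.80 ± 0.075) fell and ADM (0.82 ± 0.12) rose.

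In CWR22Rv1, Stat3 siRNA raised the laminin chain LAMC1 (1.08 ± 0.062), the hypoxia-inducible factor EPAS1 (0.91 ± 0.079), CARF (0.86 ± 0.13), WDFY1 (0.81 ± 0.092), the kinases CDK6 (0.78 ± 0.14) and DYRK2 (0.77 ± 0.11), MDFIC (0.78 ± 0.062) and the antisense transcript LPP-AS2 (0.92 ± 0.11). Lipoprotein lipase LPL (-1.59 ± 0.23), the receptor kinase AXL (-1.54 ± 0.22), the transporter SLC6A15 (-1.22 ± 0.19), the phosphatase and actin regulator PHACTR2 (-1.16 ± 0.079), BRINP3 (-1.04 ± 0.20), BCL7B (-1.03 ± 0.10) and the reticulon RTN4 (-1.0 ± 0.054) fell, each in 3 of 3 arrays like the rises, as the naming rule requires. Adjusted p was 6.7e-08 for LAMC1 and 5.6e-04 for AXL. Among the remaining large changes, HS6ST2 (-0.96) lost its call without control replicate 1 (adjusted p = 0.0526), LINC00324 (0.92) without Stat3 siRNA replicate 3 (0.05001), CCDC28A-AS1 (0.97) without 4 of the 6 arrays (up to 0.130, without control replicate 3), and LINGO1 (-0.97) without any one (up to 0.144, without Stat3 siRNA replicate 2).

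Mitotic genes rose with Stat3 siRNA in CWR22Rv1: 17 of 30 rose and 0 fell, 24 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 1.2e-17, and 0.00773 with an estimated correlation). The ubiquitin-conjugating UBE2C (0.41 ± 0.063), the spindle factor TPX2 (0.28 ± 0.055) and the transcription factor FOXM1 (0.34 ± 0.067) were among them. Replication genes gave 7 rises and 0 falls (9 and 0 adjusted over the list alone, adjusted p = 1.2e-07, and 0.0429 with an estimated correlation), with CDC6 (0.46 ± 0.058). Cyclin-dependent kinase inhibitors gave 2 rises of 7 (5 and 1 fall adjusted over the list alone), one being CDKN2B (0.41 ± 0.073), with CDKN1A at 0.33 ± 0.091 (adjusted p = 0.0512). Histones gave 2 and 0 (4 and 0 adjusted over the list alone), H1-2 (0.51 ± 0.064) and H2AC6 (0.46 ± 0.059). MAPK genes gave 2 and 0 (5 and 0) and heat shock proteins 0 and 1 (0 and 2 adjusted over the list alone). Camera adjusted p of these 4 lists was 0.0175, 0.00189, 0.00837 and 0.0188, but with an estimated correlation adjusted p was 0.111, 0.0929, 0.634 and 0.310. Member counts rested on all 6 arrays: without control replicates 1, 2 and 3 the mitotic rises numbered 8, 6 and 6 and the replication rises 2, 1 and 2, and without Stat3 siRNA replicates 1, 2 and 3 they numbered 6, 10 and 8, and 1, 3 and 3. MAPK rises and heat shock falls became 0 without any one array, and kinase inhibitor rises 1 without any one but control replicate 2. The camera calls of these lists held each time, adjusted p reaching 0.0424 for heat shock proteins. The cytokine receptor LIFR (-0.56 ± 0.093) fell, while SOCS3 measured -0.016, CISH -0.079, BIRC5 0.025, MYC -0.14 and MMP9 -0.12, none past the test.

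In CWR22Rv1, Stat5a/b siRNA raised the matrix gene MATN2 (1.41 ± 0.15), the lysosomal glycoprotein GPNMB (1.15 ± 0.11), LAMC1 (1.12 ± 0.062), the cell cycle inhibitor CDKN1A (1.10 ± 0.091), the cationic amino acid carrier SLC7A2 (1.08 ± 0.14) and the prostatic secretory protein MSMB (1.05 ± 0.17). Annexin ANXA1 (0.99 ± 0.11), histone H3C6 (0.97 ± 0.13), heme oxygenase HMOX1 (0.97 ± 0.16) and the mTOR inhibitor DDIT4L (0.95 ± 0.078) also rose. PLPPR4 (-1.85 ± 0.17), the sulfotransferase HS6ST2 (-1.59 ± 0.20), REEP3 (-1.55 ± 0.12), AXL (-1.48 ± 0.22), RAB31 (-1.19 ± 0.13), the clock gene BMAL2 (-1.15 ± 0.13), NAPB (-1.11 ± 0.077), ENPP4 (-1.09 ± 0.077), NIBAN1 (-1.04 ± 0.070) and OGFRL1 (-1.02 ± 0.086) fell. CDKN1A passed at adjusted p = 2.1e-06 and AXL at 4.6e-04, and each of these genes lay beyond control in 3 of 3 arrays, as the naming rule requires.

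Replication genes fell with Stat5a/b siRNA in CWR22Rv1: 8 of 33 fell and 0 rose, 14 and 1 adjusted over the list alone (median -0.13, camera adjusted p = 8.3e-09), among them thymidylate synthase TYMS (-0.25 ± 0.048) and the helicase subunit MCM6 (-0.22 ± 0.048). The unfolded protein and integrated stress response gave 1 rise and 10 falls (1 and 14 adjusted over the list alone, adjusted p = 5.4e-09), with VLDLR (-1.02 ± 0.11), CHAC1 (-0.67 ± 0.10) and ASNS (-0.46 ± 0.075) lower and ATF6 (0.31 ± 0.055) higher. Histones gave 3 and 0 (5 and 0 adjusted over the list alone, adjusted p = 2.2e-04), H2AC6 (0.83 ± 0.059), H2BC12 (0.49 ± 0.063) and H1-2 (0.34 ± 0.064). Without control replicates 1, 2 and 3 the falls of the stress response numbered 4, 5 and 4, and without Stat5a/b siRNA replicates 1, 2 and 3 they numbered 6, 6 and 3. Replication falls numbered 3, 5 and 3 without the control replicates, and 5 and 3 without Stat5a/b siRNA replicates 1 and 3. Camera adjusted p rose to at most 4.6e-08 and 3.4e-07 for these lists. All 3 list calls held with an estimated correlation (adjusted p = 0.0342, 0.0318 and 0.0429).

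Mitotic genes gave 0 rises and 3 falls with Stat5a/b siRNA in CWR22Rv1 (0 and 5 adjusted over the list alone), with BUB1B (-0.33 ± 0.052) and survivin BIRC5 (-0.28 ± 0.059). P53 targets gave 6 and 1 of 21 (9 and 1), with the death receptor FAS (0.44 ± 0.055), SESN1 (0.38 ± 0.064) and SUSD6 (0.33 ± 0.060), and NRF2 targets 6 and 2 (7 and 2), with NQO1 (0.94 ± 0.059) and ferritin FTL (0.53 ± 0.048) higher and TXNRD1 (-0.44 ± 0.053) lower. Luminal genes gave 2 and 1 (5 and 1, the bracketed pairs adjusted over the list alone), the splicing regulator ESRP1 (0.57 ± 0.082) and CLDN3 (0.66 ± 0.10) being higher and CDH1 measuring 0.22 ± 0.078 (adjusted p = 0.129). Camera adjusted p was 2.8e-04, 7.6e-04, 0.0102 and 0.00718, but with an estimated correlation adjusted p was 0.190, 0.104, 0.373 and 0.218. The ETS factors ETV4 (-0.64 ± 0.13) and ETV5 (-0.55 ± 0.085) and the BH3-only gene PMAIP1 (-0.61 ± 0.13) fell, and the sheddase ADAM17 (0.36 ± 0.068) rose. SOCS3 measured 0.21, BCL2L1 0.11, CCND1 -0.14, MYC 0.14, MCL1 -0.022, PIM1 -0.030 and MMP9 0.069, none past the test.

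**Figure D2:**
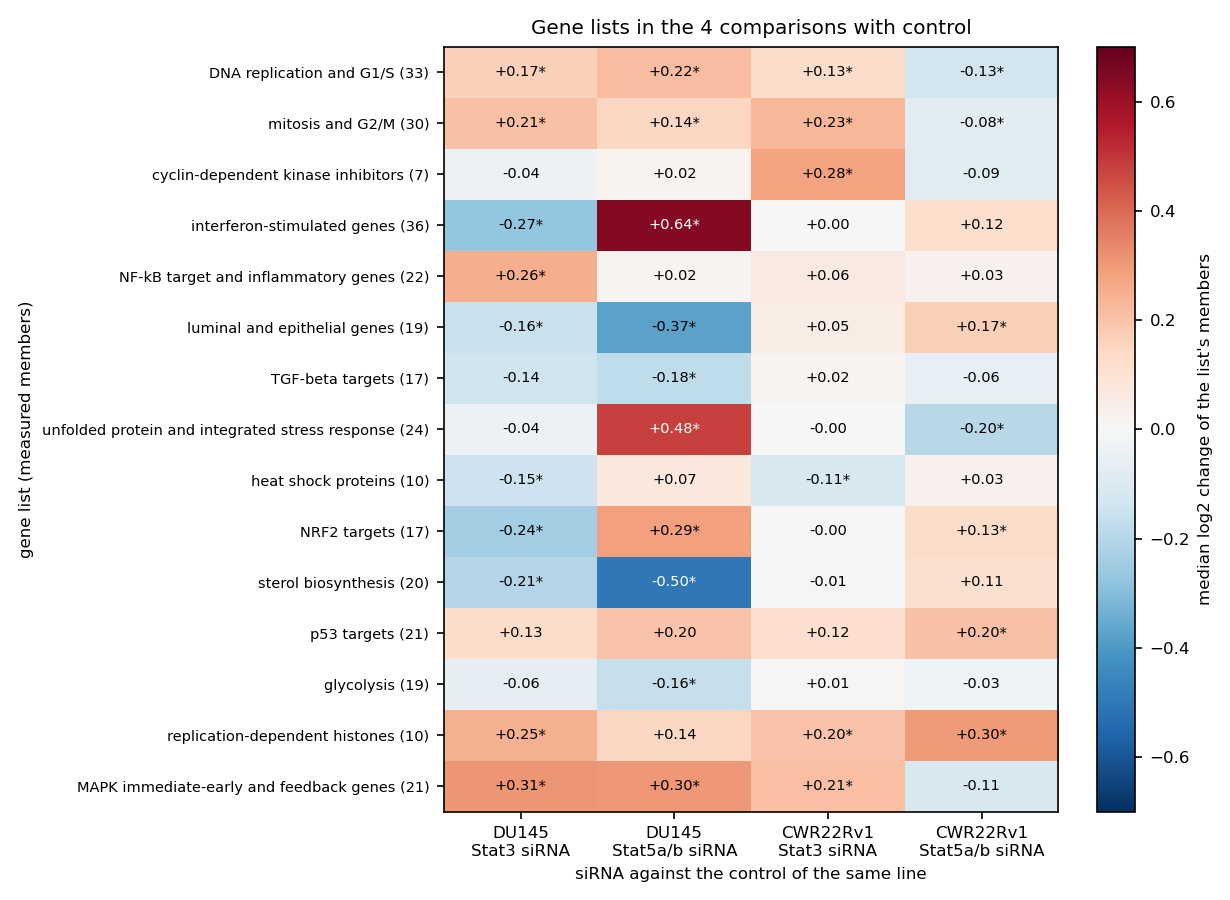
Median log2 change against control of 15 gene lists (vertical) in the 4 siRNA comparisons (horizontal), a star marking a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes stood at 0.64 with Stat5a/b siRNA in DU145 and 0.12 in CWR22Rv1, and sterol biosynthesis at -0.50 and 0.11.

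**Figure D3:**
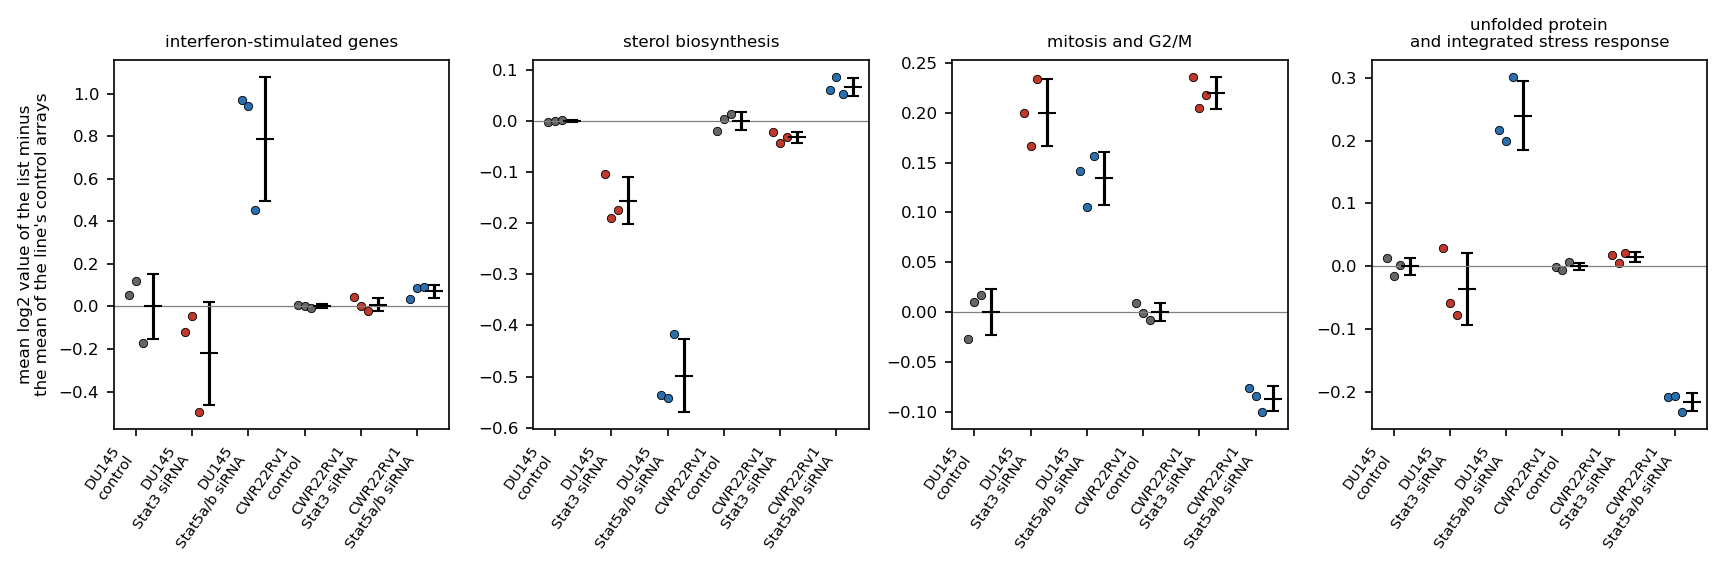
Mean log2 value of 4 gene lists on each array minus the mean of its line's control arrays, with bars at the mean ± SD of 3 arrays. The interferon list reached 0.97, 0.94 and 0.45 with Stat5a/b siRNA in DU145 and 0.044, 0.093 and 0.087 in CWR22Rv1.

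Both siRNAs were compared directly within each line. In DU145, CMPK2 (2.59 ± 0.14), MX1 (2.55 ± 0.23), IFI44 (2.04 ± 0.22), TXNIP (2.27 ± 0.096) and F2RL2 (2.46 ± 0.20) were higher with Stat5a/b than with Stat3 siRNA. TNFRSF9 (-2.15 ± 0.15), RAB31 (-1.82 ± 0.13), IFNAR1 (-1.69 ± 0.078), BCL2A1 (-1.66 ± 0.23) and CXCL8 (-1.63 ± 0.37) were lower. In total 4379 genes differed in DU145, 2167 higher and 2212 lower (2365 and 2133 after quantile normalisation), and 30.7% of genes did not overlap against 10% by chance. Fitted alone, DU145 gave 2379. Interferon genes (29 higher, 1 lower), NRF2 targets (13 and 1) and the unfolded protein response (14 and 5) stood higher, and sterol biosynthesis (0 and 12) lower. Heat shock proteins (4 and 1), NF-kB targets (0 and 5) and androgen-responsive genes (0 and 7) were also called. Adjusted over the list alone, the 7 lists gave 31 and 2, 14 and 1, 14 and 7, 0 and 14, 6 and 1, 0 and 9, and 0 and 7. Camera adjusted p was 6.6e-17, 3.5e-09, 5.8e-04, 4.0e-07, 0.0102, 0.0161 and 0.0265 in this order. With an estimated correlation adjusted p was 0.199, 0.0698, 0.119, 0.0733, 0.292, 0.337 and 0.296. The last 3 calls ended without one array, at adjusted p = 0.0515 for heat shock proteins without Stat5a/b siRNA replicate 3, and 0.0977 and 0.0688 for androgen-responsive genes without that array or Stat3 siRNA replicate 1. For NF-kB targets it was 0.0847 and 0.0524 without Stat5a/b siRNA replicates 2 and 1 and 0.0602 without Stat3 siRNA replicate 3. NF-kB members lower numbered 8 without Stat3 siRNA replicate 2 or Stat5a/b siRNA replicate 3, and sterol members 7 without Stat5a/b siRNA replicate 1.

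In CWR22Rv1, LPL (1.45 ± 0.23), the glycoprotein hormone alpha chain CGA (1.39 ± 0.24), GPNMB (1.31 ± 0.11), STAT3 (1.27 ± 0.090) and the peroxisomal CROT (1.21 ± 0.084) were higher with Stat5a/b than with Stat3 siRNA. REEP3 (-1.60 ± 0.12), the corepressor LCOR (-1.41 ± 0.092), the immediate-early EGR1 (-1.28 ± 0.20), FBXO8 (-1.25 ± 0.086) and PLPPR4 (-1.25 ± 0.17) were lower. Of 2126 differing genes 930 were higher and 1196 lower. Rescaling turned this split, to 1217 and 965 after quantile normalisation and 1182 and 977 after cyclic loess, and 36.8% of genes did not overlap against 10% by chance. Fitted alone, CWR22Rv1 gave 3775, and without Stat3 siRNA replicate 1 or 3 the count was 1388 or 1416. Mitotic genes (0 higher, 23 lower, 0 and 28 adjusted over the list alone), replication genes (0 and 20, 0 and 25) and the unfolded protein response (1 and 10, 2 and 12) stood lower with Stat5a/b siRNA. Their camera adjusted p was 2.5e-22, 1.2e-17 and 1.4e-06, and 0.00432, 0.00432 and 0.0429 with an estimated correlation. Calls of NRF2 targets (7 and 2, 8 and 2), MAPK genes (1 and 7, 2 and 7), heat shock proteins (3 and 0, 4 and 0), RNA interference genes (0 and 2, 0 and 2) and fibroblast markers (2 and 0, 4 and 0) did not hold. Their camera adjusted p was 0.0102, 6.4e-04, 0.0221, 0.0200 and 0.0315, but with an estimated correlation adjusted p was 0.373, 0.540, 0.318, 0.296 and 0.310. Heat shock proteins also missed without Stat5a/b siRNA replicate 1 (0.0524), and RNA interference genes and fibroblast markers without Stat5a/b siRNA replicate 3 (0.0556 and 0.110).

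Genes called with both siRNAs of a line mostly moved the same way. In DU145, 720 rose and 722 fell with both, where independent lists would give 175.4 and 203.8, and 231 moved in opposite directions. Shared rises were CDK6 (1.96 with Stat3 and 1.38 with Stat5a/b siRNA), MTAP (1.56 and 1.16), the lysosomal LAMP2 (1.28 and 1.34), MTMR6 (1.30 and 1.21) and DYRK2 (1.25 and 1.19). Shared falls were KRT4 (-1.77 and -2.32), FGFBP1 (-1.56 and -1.72), SELENOP (-1.45 and -1.30), autotaxin ENPP2 (-1.19 and -1.31) and GPNMB (-1.12 and -1.13). In CWR22Rv1, 155 rose and 61 fell with both, where independent lists would give 17.2 and 13.2, and 44 moved in opposite directions. LAMC1 (1.08 and 1.12) and CDK6 (0.78 and 0.84) rose, and AXL (-1.54 and -1.48), the phosphatase subunit PPP2R2B (-0.86 and -0.94), the ubiquitin hydrolase UCHL1 (-0.69 and -0.84), SLITRK4 (-0.92 and -0.75), OGFRL1 (-0.68 and -1.02) and ETNPPL (-0.68 and -0.70) fell. Without control replicate 3 the 216 genes moving the same way in CWR22Rv1 became 100, and without control replicates 1 and 2 or Stat3 siRNA replicates 1 and 3 they became 110, 112, 126 and 142.

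Both siRNAs of a line share its 3 control arrays, which alone makes their changes correlate. Across genes, which are not independent replicates, r was 0.450 in DU145 and 0.295 in CWR22Rv1, where simulated unchanged groups gave 0.499 in either line. The covariance was 0.0303 and 0.00851 against a simulated 0.00615 and 0.00618, a difference of 0.0241 and 0.00233. The simulated covariance was nearly equal in the lines, although the median gene SD of control arrays was 0.112 in DU145 and 0.0724 in CWR22Rv1. It therefore does not follow each line's own spread, and may be too low for DU145 and too high for CWR22Rv1. For that reason neither the size of these differences nor their contrast between the lines is interpreted. Simulated groups shared 0.03 calls on average in DU145 and 0 in CWR22Rv1, but unchanged groups give few calls by construction. The controls could not be halved with 2 arrays on each side, so part of the excess over independent lists may come from the shared controls.

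Changes with one siRNA met between the lines, which have separate controls. With Stat3 siRNA 338 genes rose and 255 fell in both lines, against 40.9 and 33.0 for independent lists, and 16 moved in opposite directions (one-sided Fisher's exact p = 1.2e-247 and 1.1e-177). The exact tests of these overlaps take genes as independent, which they are not, so their p overstates the certainty. LAMC1 (1.26 in DU145 and 1.08 in CWR22Rv1) and CARF (0.86 and 0.86) rose. PHACTR2 (-1.28 and -1.16), BCL7B (-1.45 and -1.03), RCN2 (-1.32 and -0.94), HMGN5 (-1.41 and -0.91), RTN4 (-0.90 and -1.0), ANKRD13C (-1.14 and -0.89) and glyoxalase GLO1 (-1.26 and -0.85) fell with STAT3. With Stat5a/b siRNA 270 rose and 364 fell in both, against 73.7 and 81.6, and 105 moved in opposite directions (p = 6.4e-91 and 1.4e-161 by the same exact test). SLC7A2 (1.08 and 1.08), HMOX1 (0.99 and 0.97) and LAMC1 (0.97 and 1.12) rose. RAB31 (-1.70 and -1.19), BMAL2 (-1.30 and -1.15), ENPP4 (-1.55 and -1.09), OGFRL1 (-1.69 and -1.02), TMEM65 (-1.23 and -1.0), GNG10 (-0.96 and -0.97) and DENND6A (-1.25 and -0.92) fell. Across genes r between the lines was 0.349 for Stat3 and 0.239 for Stat5a/b siRNA, and 0.0977 and 0.0823 when the siRNAs were crossed. Leaving out one CWR22Rv1 array left at least 326 (without control replicate 3) of the 593 genes moving alike with Stat3 siRNA, and at least 406 (without control replicate 1) of the 634 with Stat5a/b siRNA.

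**Figure D4:**
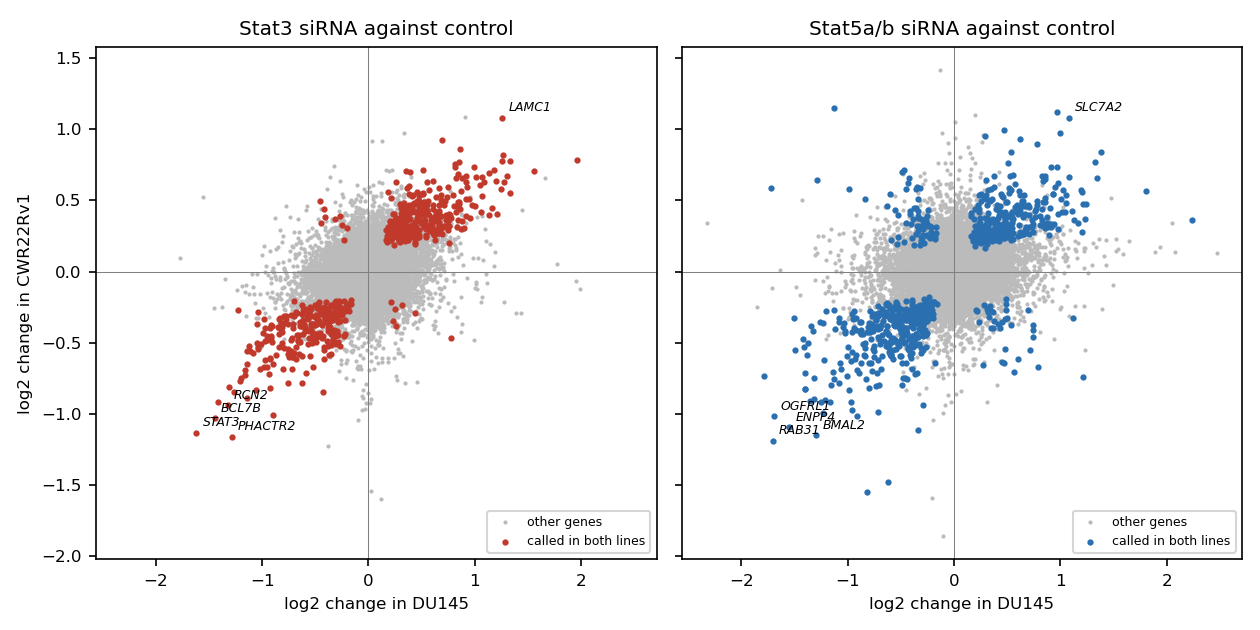
Log2 change against control in DU145 (horizontal) and CWR22Rv1 (vertical) for each gene, Stat3 siRNA on the left and Stat5a/b siRNA on the right, with genes called in both lines in colour and 5 labelled in each panel. Of the coloured genes 593 moved the same way and 16 oppositely with Stat3 siRNA, and 634 and 105 with Stat5a/b siRNA.

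The effect of an siRNA was also tested for a difference between the lines. On the probe sets used, knockdown was smaller in CWR22Rv1 by 0.49 ± 0.13 for STAT3 (adjusted p = 0.0495) and 0.45 ± 0.13 for STAT5B (adjusted p = 0.0312). With the mean of each gene's probe sets, which includes probe sets not called lower, neither differed past the threshold (0.34 ± 0.14, adjusted p = 0.226, and 0.014 ± 0.11, adjusted p = 0.960). Other probe sets called lower in both lines differed by 0.19 (adjusted p = 0.733) and 0.39 (0.296) for STAT3, and by 0.24 (0.603) and -0.11 (0.795) for STAT5B. Control values of STAT3 on the probe set used were lower in CWR22Rv1 (7.28 against 10.90), and how far they lay above background is unknown. The Stat3 siRNA effect differed for 593 genes, 359 of them higher in CWR22Rv1 than in DU145 and 234 lower, a split that became 284 and 292 after quantile normalisation and 275 and 293 after cyclic loess. With the replicate number as a block 903 genes differed. Without any one CWR22Rv1 array the count of 593, made without the block, lay between 292 (Stat3 siRNA replicate 1) and 354 (Stat3 siRNA replicate 3), and without DU145 control replicate 1 it was 371. The Stat5a/b siRNA effect differed for 2357 genes, 1335 higher and 1022 lower. List tests of this difference were added after seeing the data and adjusted among themselves. For Stat3 siRNA, luminal genes stood higher in CWR22Rv1 (5 members higher and 0 lower, 8 and 0 adjusted over the list alone, median 0.19, adjusted p = 1.5e-05, and 0.0400 with an estimated correlation). The 5 members became 2 or 3 without any one array but DU145 control replicate 3, DU145 Stat3 siRNA replicate 1 and CWR22Rv1 control replicate 1. A further 6 lists were called for Stat3 siRNA but not with an estimated correlation. NRF2 targets (2 and 0 members higher and lower), interferon genes (1 and 0), textbook STAT5 targets (0 and 0) and sterol biosynthesis (0 and 0) stood higher in CWR22Rv1, and NF-kB targets (0 and 1) and replication (0 and 3) lower. Adjusted over the list alone they gave 5 and 0, 2 and 0, 3 and 0, 0 and 0, 1 and 2, and 0 and 3. Their adjusted p was 5.1e-04, 0.0252, 0.0460, 0.0460, 0.0155 and 0.0252, and 0.400, 0.761, 0.156, 0.515, 0.400 and 0.400 with an estimated correlation. NRF2 targets kept the call without any one array, though their 2 members became 0 or 1 without any of 10 arrays, and the 3 replication members became 1 without any of 9. The other lists lost it without 3, 5, 8, 1 and 2 of the 12 arrays, at adjusted p up to 0.523 and 0.0547 (interferon genes and NF-kB targets, without DU145 Stat3 siRNA replicate 3), 0.124 (STAT5 targets, without DU145 control replicate 2), 0.126 (sterol biosynthesis, without DU145 Stat3 siRNA replicate 2) and 0.127 (replication, without DU145 Stat3 siRNA replicate 1). For Stat5a/b siRNA, luminal genes (10 and 0, median 0.38) and sterol biosynthesis (13 and 0, 0.58) stood higher in CWR22Rv1. The unfolded protein response (2 and 13, -0.67), replication (0 and 15, -0.31) and mitosis (0 and 11, -0.25) stood lower. Adjusted over the list alone these 5 lists gave 11 and 0, 15 and 0, 2 and 13, 1 and 21, and 0 and 18. Their adjusted p was 7.6e-08, 2.9e-13, 7.4e-09, 2.2e-13 and 3.7e-08, and 0.0156, 0.0140, 0.0156, 0.00995 and 0.0400 with an estimated correlation. The 11 mitotic members became 7 without DU145 control replicate 1 or any one CWR22Rv1 array but Stat5a/b siRNA replicate 3. Interferon genes gave 0 and 17 (median -0.65, adjusted p = 1.3e-10, but 0.400 with an estimated correlation). MAPK genes (1 and 6), glycolysis (2 and 0) and NRF2 targets (3 and 6) were called too (1 and 8, 2 and 0, and 4 and 8 adjusted over the list alone), at adjusted p of 1.3e-04, 0.0207 and 0.0494, but 0.546, 0.638 and 0.564 with an estimated correlation. The glycolysis call ended without DU145 control replicate 3 (adjusted p = 0.108), and that of NRF2 targets without 6 of the 12 arrays (up to 0.245, without DU145 Stat5a/b siRNA replicate 3).

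The lines differed at baseline in 11261 genes, 5926 higher in CWR22Rv1 control arrays and 5335 lower. Most prostatic and luminal genes stood higher in CWR22Rv1, among them the kallikreins KLK2 (6.59 ± 0.15) and KLK4 (5.62 ± 0.18), GRHL2 (5.57 ± 0.16), HOXB13 (4.91 ± 0.14), ACP3 (3.78 ± 0.16), TMPRSS2 (3.68 ± 0.16), ESRP1 (3.37 ± 0.082), CLDN7 (2.66 ± 0.061) and CDH1 (1.74 ± 0.078). The keratins KRT19 (-1.55 ± 0.062), KRT8 (-0.90 ± 0.10) and KRT18 (-0.43 ± 0.054) of the luminal list stood lower, as did OCLN (-1.39 ± 0.063). Of the androgen-responsive genes ABCC4 (-3.34 ± 0.089), NDRG1 (-1.29 ± 0.093) and TPD52 (-0.40 ± 0.065) also stood lower. Mesenchymal VIM (-6.02 ± 0.070), ZEB1 (-5.47 ± 0.13), TWIST2 (-3.81 ± 0.14) and S100A4 (-3.80 ± 0.16) stood lower, whereas TWIST1 (5.40 ± 0.17) stood higher. STAT3 (-3.62 ± 0.090) and STAT4 (-3.21 ± 0.25) were lower as well on the probe sets used. Other STAT3 probe sets averaged 11.28, 8.49 and 4.67 in DU145 control arrays and 6.54, 7.30 and 4.50 in CWR22Rv1, in the same order. All stood lower in CWR22Rv1, but the size of the STAT3 difference depends on the probe set. KLK3, which encodes prostate-specific antigen, measured 0.065 (adjusted p = 0.721) on the probe set used, at 6.76 in CWR22Rv1 and 6.69 in DU145. Whether that probe set reads KLK3 alone was not tested, so equal KLK3 levels are not shown. Of 36 interferon-stimulated genes 26 were lower and 5 higher in CWR22Rv1, with median levels of 5.53 there and 8.09 in DU145. Of 19 luminal genes 12 were higher and 4 lower, of 22 mesenchymal genes 6 and 11, and of 18 androgen-responsive genes 11 and 3. Line and any processing batch cannot be told apart here.

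The lists not called in any of the 6 siRNA comparisons are given as rises and falls against control for Stat3 and Stat5a/b siRNA in DU145, then Stat3 and Stat5a/b siRNA in CWR22Rv1. Other STAT genes (2 measured) gave 1 and 1, 0 and 1, 0 and 0, then 1 and 0. For JAK-STAT receptors, kinases and regulators (39 measured) the counts were 5 and 7, 1 and 9, 0 and 4, then 1 and 1. Among 29 textbook STAT3 targets they came to 2 and 5, 8 and 3, 2 and 0, then 2 and 1. Textbook STAT5 targets (20 measured) gave 1 and 3, 5 and 2, 1 and 0, then 0 and 1. For apoptosis regulators (27 measured) the counts were 5 and 3, 9 and 5, 0 and 1, then 4 and 4. Among 22 mesenchymal genes they came to 6 and 2, 3 and 4, 0 and 2, then 2 and 0. Proteases of invasion and their inhibitors (24 measured) gave 4 and 3, 1 and 3, 2 and 1, then 2 and 1. For hypoxia targets (18 measured) the counts were 2 and 4, 2 and 5, 1 and 0, then 0 and 2. Among 32 oxidative phosphorylation genes they came to 1 and 3, 1 and 3, 0 and 0, then 0 and 0. Proteasome genes (26 measured) gave 0 and 2, 2 and 2, 0 and 0, then 0 and 0. For housekeeping controls (10 measured) the counts were 0 and 2, 1 and 2, 0 and 2, then 0 and 1. Among 11 neuroendocrine markers they came to 1 and 1, 0 and 3, 0 and 0, then 0 and 0. Basal markers (8 measured) gave 1 and 0, 0 and 1, 0 and 1, then 0 and 0, and with the replicate number as a block 2 rose with Stat3 siRNA in DU145 (camera adjusted p = 0.0489). For endothelial markers (8 measured) the counts were 0 and 0, 0 and 1, 0 and 0, then 0 and 0. Among 9 leukocyte markers they came to 0 and 1, 0 and 1, 0 and 0, then 0 and 0. Cytosolic ribosomal proteins (31 measured) gave no call in any of the 4. STAT4 was lower with both siRNAs in DU145 (-0.85 ± 0.25 and -1.12 ± 0.25), as was the monocyte antigen CD14 (-1.09 ± 0.15 and -0.96 ± 0.15), both chosen after their values were seen. Lists called elsewhere gave no camera call in the remaining comparisons, for example interferon genes with 0 rises and 0 falls for Stat3 siRNA and 0 and 1 for Stat5a/b siRNA in CWR22Rv1, and sterol biosynthesis with 0 and 0, and 0 and 1. The list of siRNA targets was called in CWR22Rv1 (adjusted p = 0.00734 and 0.0352, but 0.0931 and 0.181 with an estimated correlation) and not in DU145 (0.0770 and 0.174). Adjusted over the list alone, textbook STAT3 targets gave 3 and 5, 8 and 3, 3 and 0, 2 and 1, and textbook STAT5 targets 1 and 3, 6 and 3, 3 and 0, 0 and 1 in the same order.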

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

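Of the tests weighed here, those of a single deviating array and of other splits of the arrays were set before their results were seen, and the remaining ones were chosen after. The siRNA effects that differed between the lines were singled out by a test of the difference itself. They numbered 593 genes for Stat3 siRNA and 2357 for Stat5a/b siRNA.

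For Stat3 siRNA, FGFBP1 differed by 2.08 ± 0.24 (CWR22Rv1 minus DU145), with -1.56 in DU145 and 0.52 in CWR22Rv1. The differences of the membrane-trafficking BIN1 (1.24 ± 0.21) and the carboxypeptidase inhibitor LXN (1.25 ± 0.16) ran the same way. TNFRSF9 (-2.12 ± 0.21), LINC00973 (-2.02 ± 0.27), BCL2A1 (-1.72 ± 0.32) and ADAM12 (-1.68 ± 0.12) rose in DU145 and measured -0.13, -0.067, 0.051 and -0.29 in CWR22Rv1. LPL (-1.71 ± 0.33) fell in CWR22Rv1 and measured 0.11 in DU145. KRT4 (1.86 ± 0.44, adjusted p = 0.0297) and SELENOP (1.20 ± 0.30, adjusted p = 0.0409) lost their calls when any of 10 of the 12 arrays was left out, at adjusted p up to 0.0741 (KRT4, without CWR22Rv1 Stat3 siRNA replicate 2) and 0.0925 (SELENOP, without DU145 control replicate 2).

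For Stat5a/b siRNA, GPNMB (2.27 ± 0.15) fell in DU145 (-1.13) and rose in CWR22Rv1 (1.15). KRT4 (2.66 ± 0.44), FGFBP1 (2.30 ± 0.24), the chloride channel gene CLIC3 (1.93 ± 0.19) and the desmosome-associated periplakin PPL (1.92 ± 0.23) fell in DU145 and measured 0.34, 0.58, 0.64 and 0.50 in CWR22Rv1. CMPK2 (-2.34 ± 0.20), AFAP1 (-1.94 ± 0.42) and TXNIP (-1.88 ± 0.14) rose in DU145 and measured 0.13, 0.14 and 0.36 in CWR22Rv1. TMED6 (-1.96 ± 0.21) and the lysosomal LAMP3 (-1.78 ± 0.30) measured 1.22 and 1.23 in DU145 and -0.74 and -0.55 in CWR22Rv1.

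Probe sets with several or no gene symbols, which the gene counts leave out, also changed against control. Of them 666 did with Stat3 siRNA and 1216 with Stat5a/b siRNA in DU145, and 146 and 180 in CWR22Rv1.

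Other splits of the 12 arrays bear on the line differences. Of 100 splits drawn, 5 gave as many genes as the Stat3 difference, the real one included, with up to 1160 genes against the real 593. The splits were made without the replicate number as a block, with which 903 genes differed. For Stat5a/b siRNA 2 of 100 splits gave as many, with up to 3718 against 2357, a share under 0.05. The other splits as large kept all 3 DU145 siRNA arrays together. For Stat3 siRNA they mixed the CWR22Rv1 arrays, keeping 1 of 3, and for Stat5a/b siRNA the CWR22Rv1 siRNA and control arrays changed places. They thus carry the effect of the siRNA in DU145 itself, a structure of the samples, and neither share is a test of chance.

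Interferon-stimulated genes formed one pattern to weigh: 22 of 36 rose with Stat5a/b siRNA in DU145. A single deviating array is argued against, since at least 20 members rose whichever array was left out, and low control arrays are argued against by 29 members higher than with Stat3 siRNA. With Stat3 siRNA 4 members fell against control, so part of the 29 may reflect that fall. A response to any STAT siRNA in this line is argued against because 0 members rose with Stat3 siRNA. An innate response to the Stat5a/b siRNA duplexes rather than to loss of STAT5 stays open: 0 members rose in CWR22Rv1, but the list's control level is lower there and only 1 reagent per target was used. Loss of STAT5 may equally raise these genes in DU145, and the data do not separate them.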

How the results depend on the processing

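Counts against both the control and the other siRNA were added after seeing the data. With Stat3 and Stat5a/b siRNA in DU145, then in CWR22Rv1, they were 1279, 2346, 485 and 754. Knockdown of STAT3 and STAT5B kept its direction and call under every alternative run. STAT3 lay between -1.70 and -1.57 in DU145 and -1.21 and -1.07 in CWR22Rv1 with one array left out, and STAT5B between -1.41 and -1.30, and -0.97 and -0.84. STAT5A lay between -0.33 and -0.25 in DU145 and -0.47 and -0.14 in CWR22Rv1. Its -0.30 passed in DU145 fitted alone and with the replicate number as a block, and its -0.34 in CWR22Rv1 with that block. A block on the replicate number moved the Stat3 line difference from 593 to 903 genes and no other count of genes by over 1.5 times. Beyond what stands beside the results of Stat3 siRNA in DU145, the block changed no call of a list or named gene in that comparison. Of the other pairs of groups none had all 3 same-numbered pairs of arrays correlated over 0.1: 2 did between DU145 control and Stat5a/b siRNA (0.0635 to 0.175), 0 between the DU145 siRNAs, and in CWR22Rv1 0, 1 and 0 (-0.0666 to 0.139). Each array correlated best with its own number in both control against Stat5a/b siRNA comparisons, a hint from the data, not the design. There the block called p53 targets in DU145 (adjusted p = 0.0361) and MAPK genes in CWR22Rv1 (0.0251), and in DU145 CISH (0.0365) and MYC (0.0166), whereas JUNB in CWR22Rv1 lost its call (0.33, adjusted p = 0.0544). Kinase inhibitors with Stat3 siRNA in CWR22Rv1 were not called with it (0.0575), nor was CDKN3 (0.24, adjusted p = 0.0623).

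In the order of the 4 comparisons against control, the siRNA contrasts in DU145 and CWR22Rv1 and the Stat3 and Stat5a/b line differences, at least 1.5-fold changes numbered 603, 927, 125, 188, 826, 271, 239 and 852. At an adjusted p under 0.01 the counts were 1789, 3002, 366, 596, 2628, 1100, 126 and 1035. With one line fitted alone, the first 6 were 1549, 2877, 2059, 2372, 2379 and 3775, the spread being larger in DU145. Array weights gave 2980 and 2644 in CWR22Rv1, 4135 between its siRNAs and 3584 for the Stat5a/b line difference. The Stat3 line difference became 904 with a trended robust variance and 382 with all probe sets tested. With one array left out the 8 counts ran from 2457 to 3075, 3676 to 4867, 448 to 547, 718 to 844, 3590 to 4326, 1388 to 1640, 292 to 780 and 1677 to 2694. The cause of these moves was not tested, except that stricter thresholds call fewer genes by construction.

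Genes moving alike with both siRNAs in DU145 (1442) were 690 with the line alone, 209 at 1.5-fold and 768 at 0.01, and 1068 to 1523 with one array left out. Those in CWR22Rv1 (216) were 523 with the line alone, 140 with the mean of a gene's probe sets, 694 with weights, 23 at 1.5-fold, 86 at 0.01 and 100 to 149. Those shared by the lines were 1030, 64 and 248 for Stat3 siRNA with weights, at 1.5-fold and at 0.01, and 326 to 596 with one array left out. For Stat5a/b siRNA they were 1057, 70, 330 and 406 to 710.

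Called lists, 10, 10, 7 and 8 against control and 7 and 8 between siRNAs, became 2, 1, 2, 3, 0 and 3 with an estimated correlation. By fry, which asks another question, they were 19, 22, 9, 13, 19 and 19. With one array left out they ran from 9 to 12, 9 to 12, 7 to 7, 8 to 9, 6 to 8 and 6 to 8.

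Of 2490 values of named genes with one array left out, 2252 kept direction and call, 226 lost the call, 2 gained it and 10 changed sign. Each of the other settings held 395 values, each for a named gene in a given comparison, so some genes recur. Lost calls numbered 42 with the mean of probe sets, 33 with the line alone, 9 with weights and 7 with quantile normalisation. They numbered 6 with loess, 3 with the trend and 2 with the block. Sign changes, with no call in either setting unless stated, were SOCS3 with Stat3 siRNA in DU145 (-0.23 to 0.061 over the arrays left out) and BIRC5 (-0.011 to 0.089). SOCS3 with Stat5a/b siRNA in DU145 became 0.0017 after quantile normalisation, 0.020 with weights, and ran from -0.076 to 0.078 with one array left out. In CWR22Rv1, SOCS3 with Stat3 siRNA ran from -0.070 to 0.066, and with Stat5a/b siRNA PIM1 ran from -0.064 to 0.031 and MMP9 from -0.033 to 0.16. With the mean of a gene's probe sets, BCL2L1 became 0.0061 with Stat3 siRNA in DU145, and with Stat5a/b siRNA there BIRC5 became -0.00092 and KLK3 -0.18. AURKB (-0.075), NDUFC1 (0.038) and PSMA5 (0.014), called with their own probe set, turned in that setting and lost the call, and other probe sets of NDUFC1 include one called the opposite way (0.34, adjusted p = 0.0374). Over called named genes, 395 of 459 other probe sets had the same sign. The cause was not tested. Array signal over background was not assessed here, so how dim a gene can be measured is unknown.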

Other observations

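The test of noise from shared controls, that of an excess of rises and the chance overlap tests were chosen after the results were seen, and the tests of scramble lowering, of direct silencing and of other splits before. Genes that changed the same way with both siRNAs in both lines were counted after the 4 comparisons were made, and those named here beyond LAMC1, CDK6 and OGFRL1 were chosen after their values were seen. They were 95 rises and 22 falls. LAMC1 rose by 1.26 and 0.97 with Stat3 and Stat5a/b siRNA in DU145 and by 1.08 and 1.12 in CWR22Rv1, and LAMP2, the snRNP assembly factor GEMIN5 and SH3D19 also rose in all 4 comparisons, as did CDK6. The falls held OGFRL1, CEMIP2, the drug efflux pump ABCG2, ABHD13, DCAF7 and the RNase DICER1 (-0.38 and -0.43 in DU145, -0.38 and -0.53 in CWR22Rv1), which cuts microRNA precursors.

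These shared rises were weighed as a pattern. Independent lists in the 2 lines would give 5.64 shared rises and 2.23 falls, and each line has its own control arrays, so the 95 rises argue against noise of the shared controls as the source. Rises made up 81.2% of the 117 shared changes (exact 95% interval 72.9% to 87.8%, taking genes as independent, which they are not). The split was not recounted after rescaling, which turned the balance of rises and falls in each comparison against control. An excess of rises is what a scramble siRNA that lowered some transcripts in the controls would give. That explanation also needs the rises to differ between siRNAs less often than the falls: 46.3% of rises and 59.1% of falls did (two-sided Fisher's exact p = 0.346), which leaves it open. Of all genes 27.3% differed between the siRNAs, a share under that of the rises, but it includes genes not called against control. A common effect of losing either STAT, or of any active siRNA, was not separable from it.

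Changes that one siRNA shared between the lines were weighed as another pattern. Falls in both lines numbered 255 for Stat3 and 364 for Stat5a/b siRNA, against 33.0 and 81.6 for independent lists, which argues against chance overlap. Among genes called the same way in both lines against control and against the other siRNA, 142 fell and 90 rose for Stat3 siRNA (61.2% falls, exact 95% interval 54.6% to 67.5%), and 243 fell and 71 rose for Stat5a/b siRNA (77.4%, 72.4% to 81.9%). Both intervals take genes as independent, which they are not, and the counts were not repeated after rescaling. An excess of falls is what direct silencing of other transcripts by the siRNA would give, and it may account for part of these changes. Genes that need STAT3 or STAT5 for their expression would fall too, so this biological explanation stays open.

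Splits of the 6 arrays of a comparison number 10, the real one included, too few for a share under 0.05. The real split gave 3117, 4805, 944 and 1277 genes against control, in the order Stat3 and Stat5a/b siRNA in DU145, then in CWR22Rv1, and the highest other split 21, 1, 0 and 0. Between the siRNAs it gave 4379 in DU145 and 2126 in CWR22Rv1, against 27 and 0. In each of these 6 only 1 split, the real one, gave as many genes. Every other split mixes siRNA and control arrays, so a large siRNA effect enters the spread within its groups and leaves few calls. The gene counts of the other splits are therefore not those of unchanged groups and do not test chance. Lists called against control numbered 10, 10, 7 and 8 in the real split and up to 7, 8, 2 and 3 in another. Between the siRNAs they numbered 7 in DU145, where 2 splits gave as many, and 8 in CWR22Rv1, where another split gave up to 4.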
